A study of Drosophila melanogaster with 6 samples.

How the data were processed

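Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where Yorkie (Yki) lies on the genome of Drosophila melanogaster embryos aged 8 to 16 h. Yki is the transcriptional coactivator at the end of the Hippo growth-control pathway, and it reaches DNA through partners such as Scalloped. Per the labels, embryos of a y; cn bw sp strain were crosslinked in 1.8% formaldehyde for 15 min, and chromatin was precipitated with a rabbit polyclonal antiserum raised against full-length Yki. The series holds 3 Yki ChIP libraries and 3 input libraries. The labels do not say whether the libraries of a group came from separate embryo collections.

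The deposited result is 1 peak list for the whole series, with a start, an end and 1 peak score per peak, and without summits, fold enrichments or values per library. The peak score is the value deposited by the authors for each peak, and its scale is not given in the sources used here. It was therefore used only to rank and filter peaks within this list and to compare groups of peaks within it. Per the file headers, the coordinates follow FlyBase release 5 and the peaks came from MACS. The submitters' processing notes name CASAVA 1.7.0.2 and 1.7.0.3, BWA, MACS2 and the build BDGP5, with no parameters. How the 3 ChIP and 3 input libraries were combined before peak calling is not given in the sources used here. The number of reads per library is unknown from the list, so no depth, floor or replicate spread can be given, and no result below has a replicate check. Intervals cover counting error over peaks only.

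Peaks were counted per sequence of the assembly, and all coordinates are 1-based release 5 positions. The 6 chromosome arms are 2L, 2R, 3L, 3R, 4 and X. Sequences ending in Het hold heterochromatic scaffolds assigned to a chromosome, and U and Uextra hold scaffolds assigned to none, joined end to end. The furthest peak end on each sequence stood for its length, which understates sequences with few peaks. The peak count of each of the 14 nuclear sequences was compared with its share of the summed length by a two-sided exact binomial test with Benjamini-Hochberg adjustment. The mitochondrial genome was left out of that family. Clustering was measured as the share of peaks whose nearest neighbour on the same sequence lay within 10 kb, against 1000 random placements that kept the number of peaks, their widths, the first and last peak and a gap of at least 50 bp, as a one-sided permutation test whose smallest p is 0.000999. Median peak scores were compared with two-sided permutation tests of 100000 resamples, with bootstrap intervals of 2000 draws. Shares have exact Clopper-Pearson 95% intervals. Peaks are not independent replicates, and clustered peaks make binomial p-values too small, so runs of peaks with gaps of at most 10 kb were also counted once.

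The tests were checked on simulated data. The clustering test called 21 of 400 uniform placements of 3182 peaks on the 6 arms and 400 of 400 in which a share of the gaps had been shortened. The arm test for chromosome 4 called 21 of 400 uniform draws and 399 of 400 draws with its density doubled, again over 3182 peaks. The uniform placements came from the same procedure as the random placements of the clustering test. The draws per arm were independent, as the binomial test assumes. They therefore cannot show the error rate of the arm test for clustered peaks. The coverage autocorrelation used in the closing section found a built-in period in 20 of 20 simulations and called 2 of 20 random arrangements of 50 peaks. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

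The comparisons of peak number and width, peaks per sequence, clustering and X against autosomal scores, their alternatives and the rule for named items were fixed before the data were examined. The score comparisons and Fisher's exact tests of chromosome 4, U with the Het sequences, and Uextra against the arms were chosen after seeing the data. Because gene coordinates of release 5 were not used here and the gene table at hand follows release 6, the rule's version without annotation applied: the 20 highest-scoring peaks, the 5 widest peaks and the 5 windows of 100 kb with the most peaks are named by position. For the same reason the planned comparisons with promoters and gene features, the 25 fixed gene lists and the 14 sequence motifs were not run. Alternatives were the 50% and the 25% of peaks with the highest scores, neighbour distances of 5 and 20 kb, merging of touching peaks and restriction to the 6 arms. The others were chosen after seeing the data: counting runs once, the 6 arms alone in the clustering test, leaving out the 2 densest 100 kb windows of the arms (in the arm test together with the restriction to the 6 arms, and with the length of the windows also left out), leaving out the 25% of peaks with the lowest scores for chromosome 4, and leaving out the stretch of Uextra from 28 to 29 Mb.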

Results

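Yki occupancy was profiled by ChIP-seq in 8 to 16 h embryos, from 3 Yki ChIP libraries and 3 input libraries, to find the genomic sites that the Hippo pathway coactivator Yki occupies during mid-embryogenesis. The comparison of ChIP with input is summarised in a single list of 5136 peaks, in which each peak has a position and 1 score from the authors' peak caller. The list holds no values per library, so the spread between the replicates could not be measured. Peaks were not assigned to genes here, and sites are given as release 5 positions.

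The peaks covered 2657878 bp in total and were narrow, with a median width of 408 bp (95% interval of the median 401 to 415 bp) and quartiles of 292 and 590 bp. Widths ran from 201 to 5649 bp, and scores from 5.94 to 537.36 around a median of 30.1. The 6 chromosome arms held 3182 peaks, or 62.0% of the list (exact 95% interval 60.6 to 63.3%). A further 1713 peaks, 33.4% (32.1 to 34.7%), lay on Uextra, a collection of scaffolds that were not assigned to a chromosome. U and the Het sequences held 239 peaks, or 4.65% (4.09 to 5.27%). The remaining 2 peaks were on the mitochondrial genome. Wider peaks had higher scores, with a Spearman correlation across peaks of 0.64 and a Pearson correlation of 0.44; peaks are not independent replicates, so no p is given.

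The strongest Yki sites were spread over the large autosomal arms and the heterochromatic and unassigned scaffolds. The highest score in the list, 537.36, belonged to a peak of 1087 bp on 2LHet at 367856 to 368942. That peak was the last of 7 on 2LHet, where the median score was 14.3. Next in score came a peak on 2R at 15993724 to 15994436 with 532.03 and a peak on 2L at 14490093 to 14491348 with 489.6. A peak on 2R at 18401270 to 18402533 with 485.83 and a peak on 3R at 27538590 to 27539883 with 472.97 came after them. Of the 20 highest-scoring peaks, 13 lay on the 6 arms. Arm 2R had 6 of them, and the other 4 on this arm were at 9812790 to 9813394, 15517913 to 15518877, 18157685 to 18158857 and 4553343 to 4556747. Arm 3R had 3, including the sites at 7599096 to 7600180 and 25597488 to 25600749. On 3L the sites were at 14747927 to 14753575 and 14266970 to 14267669, and the remaining site on 2L was at 5236955 to 5237904. U held 1 of the 20, at 9934441 to 9935082, and Uextra held 5, at 26710293 to 26710789, 28595521 to 28596127, 26311023 to 26311704, 8455757 to 8456222 and 28638807 to 28639321. The X and chromosome 4 had none of the 20, and their highest scores were 367.89 and 170.4.

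Width and strength did not always go together. The widest peak, 5649 bp on 3L at 14747927 to 14753575, was also among the 20 strongest, with a score of 420.87. The next 3 in width had much lower scores. They were a peak of 4837 bp on 2L at 6992184 to 6997020 with a score of 20.88, a peak of 4818 bp on 3R at 873135 to 877952 with 25.07 and a peak of 4039 bp on 2L at 12559057 to 12563095 with 31.57. The fifth, 3715 bp on 2R at 8474158 to 8477872, scored 155.44.

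Across all 14 nuclear sequences, Uextra carried the highest density of Yki peaks and the large scaffolds of placed heterochromatin the lowest. Uextra had 59.1 peaks per Mb, 1.93 times its share by length (95% interval 1.86 to 2.01, exact binomial test, adjusted p = 4.07e-169), and 46.2 peaks per Mb without its densest stretch at 28 to 29 Mb. Densities on 2RHet, 3LHet and 3RHet were 11.4, 11.8 and 11.7 peaks per Mb, with observed over expected ratios of 0.374, 0.385 and 0.382 and adjusted p-values of 5.27e-12, 3.13e-08 and 1.31e-08 in the exact binomial test. U had 13.2 peaks per Mb, at a ratio of 0.430 (exact binomial test, adjusted p = 1.15e-29). No length was corrected for the part that reads can be mapped to. A low density therefore need not mean that Yki avoids a sequence. XHet, YHet and 2LHet had only 5, 5 and 7 peaks and did not pass the test, with adjusted p-values of 0.840, 0.669 and 0.273. With Uextra in the total, 2L, 3L, 3R and X fell below their shares at ratios of 0.828, 0.869, 0.865 and 0.796, with adjusted p-values of 1.06e-06, 0.000121, 2.15e-05 and 1.19e-08 in the exact binomial test, and 2R (0.947, adjusted p = 0.202) and chromosome 4 (1.24, adjusted p = 0.191) did not pass the test. The calls of 3L and 3R ended with runs of peaks counted once (exact test, adjusted p = 0.463 and 0.709) and without the Uextra stretch (0.123 and 0.0791), and that of 3R also in the strongest 50% of the list (0.383). In the strongest 25% of the list chromosome 4 fell below its share (0.291, exact test, adjusted p = 0.0244), with 3 peaks.

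**Figure D1:**
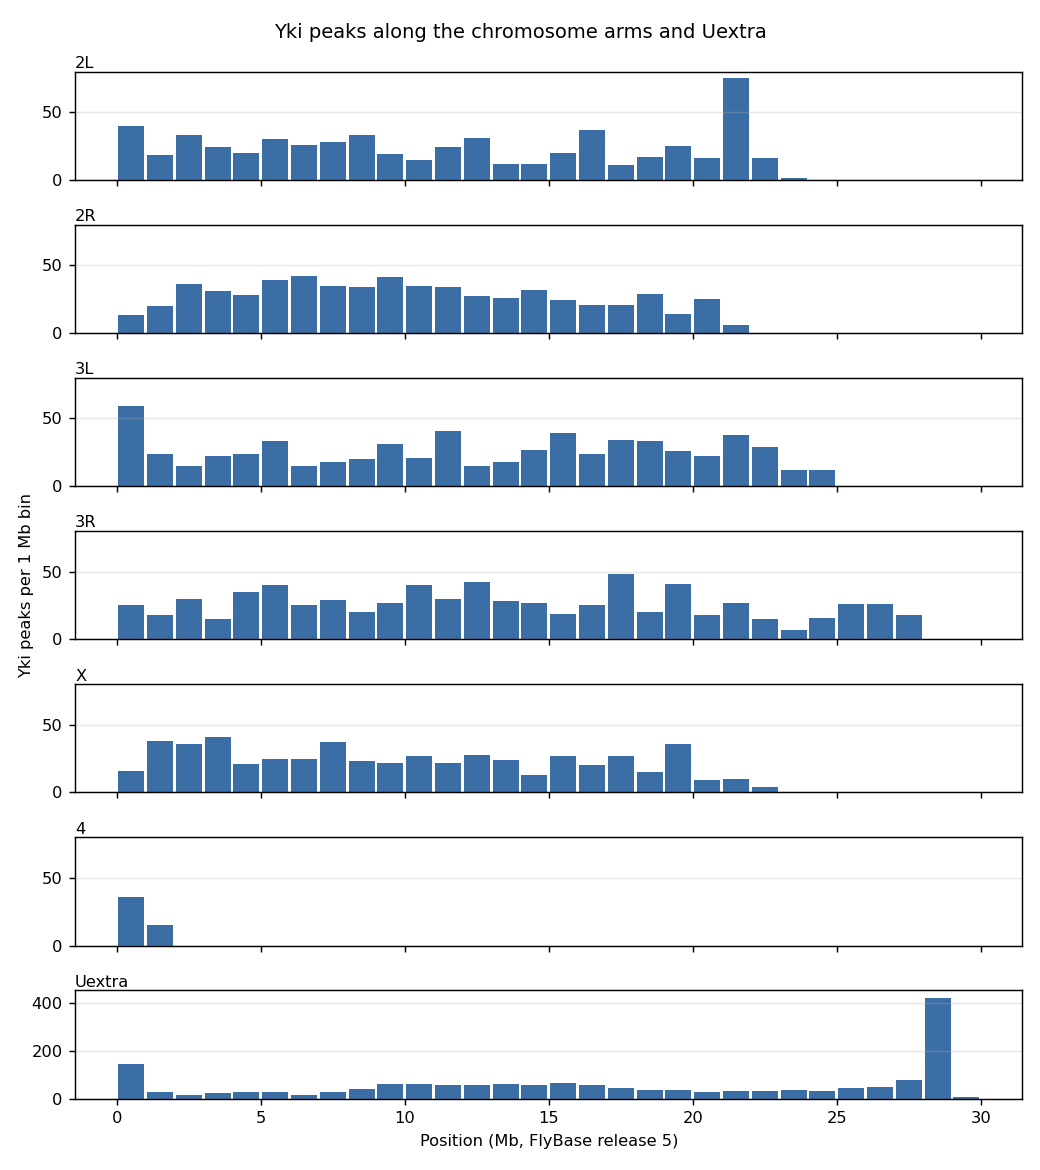
Number of Yki peaks (y axis) in bins of 1 Mb (x axis, position in Mb, FlyBase release 5) on the 6 arms, drawn on a common y axis, and on Uextra, drawn on its own larger y axis. The bin from 28 to 29 Mb of Uextra holds 418 peaks, and the bin from 21 to 22 Mb stands above the rest of 2L with 75 peaks.

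Among the 6 arms alone, densities lay much closer together. Arm 2R had 28.99 peaks per Mb, 2L 25.3, 3L 26.6, 3R 26.5 and X 24.4, while the small, largely heterochromatic chromosome 4 had the highest density, 37.8 peaks per Mb from 51 peaks. Chromosome 4 exceeded its share by 1.43 times (95% interval 1.07 to 1.88, exact binomial test, adjusted p = 0.0425) and 2R by 1.10 times (1.02 to 1.18, adjusted p = 0.0425). The X, at 0.921 (0.851 to 0.993, adjusted p = 0.0647), 2L (0.958, adjusted p = 0.390), 3L (1.00, adjusted p = 0.983) and 3R (1.00, adjusted p = 0.983) did not pass the exact test. Whether these ratios passed the test depended on how peaks were counted. In the strongest 50% and 25% of the list, neither 2R (1.14 and 1.18, adjusted p = 0.0634 and 0.145) nor chromosome 4 (0.611 and 0.357, adjusted p = 0.149 and 0.168) passed the exact test. The ratio of 2R did not fall in these smaller lists, which held 1607 and 751 peaks on the arms, while chromosome 4 went below its share. With runs of peaks counted once in the exact test, chromosome 4 no longer passed (ratio 1.39, adjusted p = 0.155), 2R did (1.14, adjusted p = 0.0152) and X fell below its share (0.859, adjusted p = 0.0152). Without its 2 densest windows of 100 kb, 2L was below its share (0.885, 95% interval 0.817 to 0.956, exact test, adjusted p = 0.0106), but these windows were picked for their peak number, so leaving them out was bound to lower 2L.

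**Figure D2:**
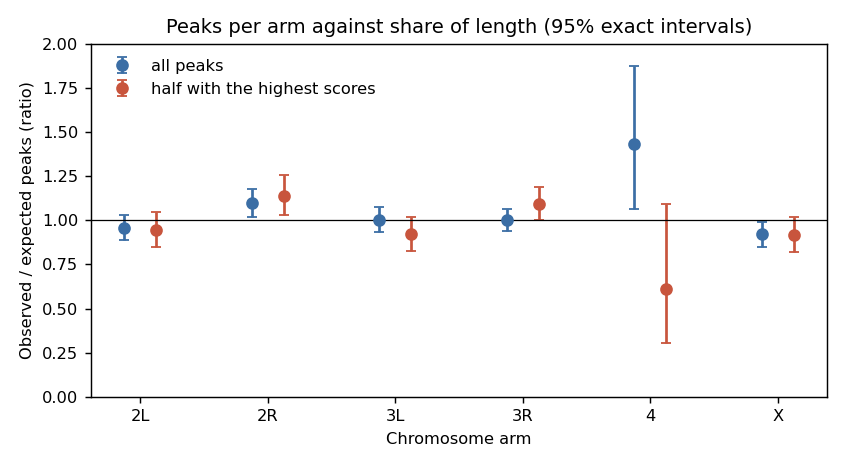
Observed over expected number of Yki peaks (y axis, ratio to the share of length) on each of the 6 arms (x axis), for all peaks and for the 50% of the list with the highest scores. Points are ratios and bars are exact 95% intervals; chromosome 4 lies at 1.43 with all peaks and at 0.611 with the stronger 50%.

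Peak strength differed between classes of sequence, in comparisons chosen after seeing the data. Peaks on U and the Het sequences were weak, with a median score of 16.6 against 30.7 on the 6 arms, a difference of -14.1 (bootstrap 95% interval -16.6 to -12.3, permutation p = 3e-05, adjusted p = 0.00013). The median on Uextra was 35.9, higher than on the arms by 5.22 (2.17 to 8.56, permutation p = 0.00054, adjusted p = 0.0014), but this rested on 1 stretch. Without the 418 peaks at 28 to 29 Mb, the other 1295 peaks of Uextra had a median of 22.5, below that of the arms by a difference of -8.22 (-10.3 to -5.84, permutation p = 1e-05, the smallest possible), and 19 of its 30 bins of 1 Mb had a median under that of the arms. The stretch was picked because it stands out, and no peaks were left out of the arms. Leaving it out was therefore bound to lower Uextra, and this p is descriptive only. The median on chromosome 4 was 18.6 against 31.0 on the other arms, a difference of -12.4 (-15.8 to -9.10); the permutation p was 0.0524 and did not pass the test after adjustment over 13 such comparisons (0.0973). Of the 51 peaks on chromosome 4, 11 belonged to the 50% of the list with the highest scores, or 21.6%, compared with 1596 of 3131 peaks, or 50.97%, on the other arms (Fisher's exact test, two-sided, adjusted p = 4.07e-05). The same share was 15.9% on U and the Het sequences, below the 50.5% of the 6 arms (Fisher's exact test, adjusted p = 1.17e-26), and 53.9% on Uextra, above it (adjusted p = 0.0245), where it was 40.8% and below the arms without the stretch at 28 to 29 Mb (Fisher's exact test, p = 5.00e-09). For the reason given above, the p without the stretch is descriptive only.

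No difference in peak strength between the X and the autosomal arms was detected. The median score was 30.4 over 546 peaks on the X and 31.0 over 2585 peaks on 2L, 2R, 3L and 3R. The difference of -0.63 (X minus autosomal arms, bootstrap 95% interval -3.17 to 3.70) did not pass the two-sided permutation test (p = 0.738).

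**Figure D3:**
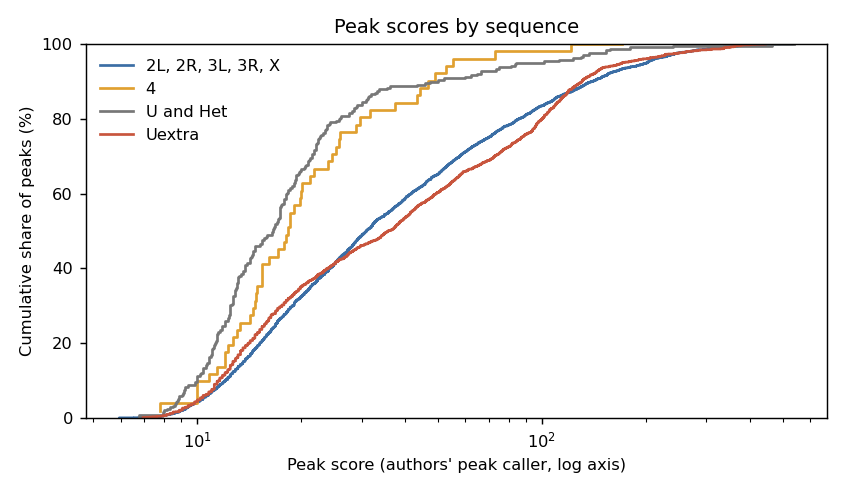
Cumulative share of peaks (y axis, %) by peak score (x axis, log scale, the authors' peak caller), with 1 line each for the large arms, chromosome 4, U with the Het sequences, and Uextra. The lines of chromosome 4 and of U with the Het sequences lie to the left of the large arms, with medians of 18.6 and 16.6.

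Yki peaks lay closer together than random placements on the same sequences. Of the 5134 nuclear peaks, 3441, or 67.0% (exact 95% interval 65.7 to 68.3%), had another peak within 10 kb, compared with a mean of 50.1% and a highest value of 52.3% over 1000 random placements (one-sided permutation p = 0.000999, the smallest they can give). On the 6 arms the share was 63.4% against 41.4% at random. It was highest among the large arms on the X, at 68.5% against 38.7%, and was 63.3% against 39.99% on 2L, 60.8% against 44.1% on 2R, 62.9% against 41.4% on 3L and 61.9% against 41.3% on 3R, each with a permutation p = 0.000999. Chromosome 4 reached 68.6% against 53.3% (permutation p = 0.0340). On Uextra, where random placements already gave 70.1%, the share was 74.5% (permutation p = 0.000999). U and Uextra are scaffolds joined end to end, so distances on them need not be distances in the genome. The values of the 6 arms are free of this limit, and those of all nuclear peaks are not. Joined at gaps of up to 10 kb, the peaks of the 6 arms formed 697 runs of at least 2 peaks and 1165 single peaks. In windows of 100 kb on the arms, the variance of the peak number was 2.65 times its mean of 2.64, and 18.6% of windows held no peak, where a Poisson distribution of that mean gives 7.13%.

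The named 5 densest windows of 100 kb all lay side by side on Uextra, from 28.5 to 29 Mb, with 46, 54, 63, 74 and 82 peaks in order of position and median scores of 105, 105, 93.7, 86.8 and 99.0. Because Uextra joins scaffolds end to end, these windows need not be neighbours in the genome. On the arms, windows were chosen after their values were seen. The densest held 35 peaks at 21400001 to 21500000 on 2L and 23 in the next window, and was followed by the first 0.1 Mb of 3L with 19 peaks and by 17.4 to 17.5 Mb on 3R with 16. The longest runs outside these were 13 peaks over 30.5 kb on 2R at 6421568 to 6452103, with a highest score of 225.25, and 11 peaks over 34.9 kb on 2L at 16513585 to 16548478, with a highest score of 270.82. A compact run on the X at 2187341 to 2200704 held 9 peaks with a median score of 129.

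**Figure D4:**
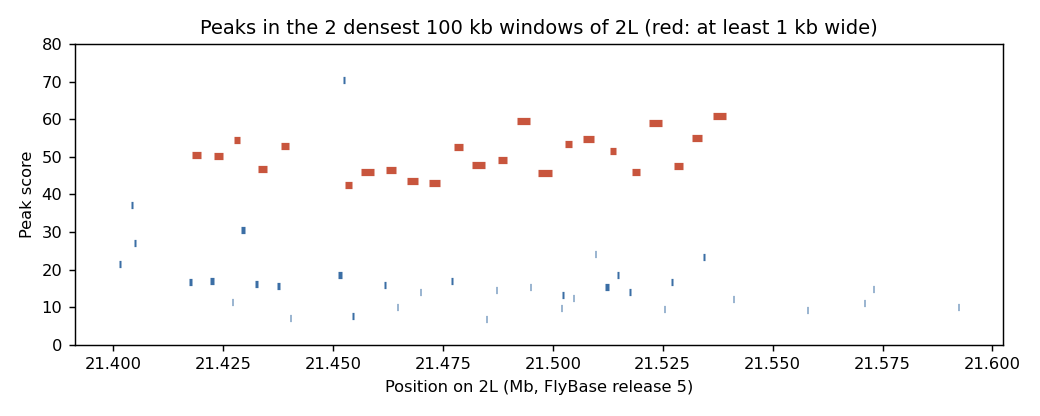
Score (y axis, the authors' peak caller) and extent (x axis, position in Mb on 2L, FlyBase release 5) of each peak in the 2 densest 100 kb windows of 2L, with peaks at least 1 kb wide in red and narrower peaks in blue. The 23 wide peaks recur along the block with scores from 42.6 to 60.97.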

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

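The mitochondrial genome was left out of the tests per sequence and of clustering, and its peaks entered only the totals, widths, scores and ranks of the whole list. On it, 2 peaks were called over input, at 8657 to 8863 with a score of 20.36 and at 14416 to 14618 with a score of 22.03. No other result met a rule for a closer look, since the list holds no values per library.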

How the results depend on the processing

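The clustering of peaks (past the threshold) and the difference in score between X and autosomal arms (not past it) kept their direction and side of the threshold under every alternative run for them. The share with a neighbour was 52.3% and 45.4% in the strongest 50% and 25% of the list (random means 32.3% and 19.5%), 53.3% and 80.6% at 5 and 20 kb, 66.7% without the 2 densest windows and 64.2% without the Uextra stretch at 28 to 29 Mb. The density on Uextra stayed above its share in the 4 alternatives that include it. By construction, the strongest 50% held 2568 peaks, with a median width of 535 bp, and merging touching peaks changed nothing. Restricting the arm test to the 6 arms moved 2L to 0.958 and X to 0.9205, no longer past the threshold, and chromosome 4 to 1.4306, now past it. The same restriction turned 2R to 1.096, 3L to 1.0048 and 3R to 1.0007. Uextra, U and the Het sequences then leave the total together. Of the alternatives chosen after seeing the data, restricting to the 6 arms and also leaving out the peaks and the length of the 2 densest windows, which were changed together, gave 2R 1.1144, 3L 1.0218, 3R 1.0176, chromosome 4 1.4547, X 0.9361 and 2L 0.8849, where 2L passed the threshold (exact test, adjusted p = 0.0106) as it did not with the 6 arms alone; both windows were picked for their peak number and lie on 2L, so leaving them out was bound to lower it. Counting runs once over all 14 sequences gave 2R 1.0831, 3L 0.9536 and 3R 0.9765, and leaving out the Uextra stretch gave 2R 1.0252, 3L 0.94 and 3R 0.9361. Under the last pair of settings 3L and 3R no longer passed the threshold. In the strongest 50%, 3R was at 0.9527, no longer past the threshold, and chromosome 4 at 0.5333, and in the strongest 25% chromosome 4 was at 0.2909, now below its share and past the threshold (exact test, adjusted p = 0.0244); for 3R the cause was not tested. YHet, with 5 peaks, went from 1.19 to 0.9503 and 0 (no peak) in the strongest 50% and 25%. No paired analysis was possible because the list gives 1 score per peak and no values per replicate, and for the same reason no replicate could be left out. The alternatives on distance to transcription start sites, gene lists, motif windows and summits were not run. Depth per library is unknown, so it is not known which weak sites the depth hid.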

Other observations

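All tests in this part were chosen after the peak list had been seen. Scores of neighbouring Yki peaks on the 6 arms were only weakly correlated. Across the 1320 adjacent pairs of peaks within 10 kb of each other, the Spearman correlation of their scores was 0.11 and Pearson's 0.09 (permutation p = 0.0001, the smallest possible here, adjusted p = 0.00012), and it was 0.11 as well across the 1856 adjacent pairs further apart; the difference was not tested. On Uextra the Spearman correlations were 0.49 for 972 pairs within 10 kb and 0.09 for 740 pairs further apart (6 relations computed, permutation p = 0.0001 and 0.0124). Pearson's were 0.31 and 0.08. These are correlations across peaks, which are not independent replicates. Uextra holds stretches at unlike score levels, such as its first Mb (145 peaks, median 15.2) and 28 to 29 Mb (418 peaks, median 96.0). Such differences in level can by themselves give a correlation among close pairs, and the correlation was not computed without those stretches.

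As a set, the stretches of 5 arms next to the centromeres held fewer and weaker peaks. How much of them reads can be mapped to was not taken into account, so this need not mean less Yki there. The proximal 1 Mb of 2L, 2R, 3L, 3R and X together held 79 peaks, or 15.8 per Mb, against 26.8 per Mb over the rest of these arms (exact binomial p = 7.05e-07), and their median score was 16.7 against 31.6 (permutation p = 0.0117, adjusted p = 0.0253). The median was lower in the proximal stretch on 2L, 2R, 3L and X, with 11 to 17 peaks each and no single arm passing the permutation test, and was 37.5 over 25 peaks against 33.3 on 3R; differences between the arms, and the density of each arm's stretch, were not tested. At the distal ends, 2L opened with 4 peaks covering 91.7% of its first 6 kb and 27.5% of its first 20 kb, and 3L with 6 peaks covering 81.75% of its first 6 kb and 17 peaks covering 87.7% of its first 20 kb; the distal ends of 2R and 3R were not examined. Their scores stayed between 17.12 and 26.68 on 2L and between 12.91 and 23.12 on 3L, while the first peak on the X began only at 13969.

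The densest block on the arms, 58 peaks between 21401365 and 21592374 on 2L, showed a repeating layout. The 23 peaks of at least 1 kb followed one another at a median spacing of 5037 bp between 21417937 and 21539419 with scores of 42.6 to 60.97, and the coverage by all 58 peaks repeated at a lag of 5040 bp with an autocorrelation of 0.6845, against at most 0.243 in 1000 random placements of the same peaks (permutation p = 0.000999). The midpoints of all 58 peaks did not share 1 phase beyond chance (permutation p = 0.0729), while those of the 23 wide peaks did (0.000999). The width cutoff of 1 kb was set after the list had been seen, so the second p is descriptive only. Of the 8 next densest windows, 2 had an autocorrelation above that of random placements. It was 0.719 at the first 0.1 Mb of 3L and 0.330 at 16.5 to 16.6 Mb on 2L (permutation test, adjusted p = 0.00799 and 0.0120). The lags, 2000 and 2600 bp, were at or near the shortest searched. Random placements do not keep clumps, and on 3L 17 peaks covered 87.7% of the first 20 kb. At such lags the test cannot tell a clump of peaks from a repeat. The median score of the block, 22.475 (95% interval 16.2 to 43.7), lay below the 69.2 that opens the top 25% of scores on the arms, which argues against a cluster of the strongest sites. A tandem repeat whose copies share reads is a candidate explanation; the tandem array of histone genes is known to lie on proximal 2L, but whether the block is that array, and whether Yki occupies it, was not tested.

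The excess of peaks on Uextra had more than 1 component and was not confined to its first Mb and the stretch at 28 to 29 Mb. Without the stretch at 28 to 29 Mb, Uextra still had 46.2 peaks per Mb, but this value includes the first Mb. The density without both stretches was not computed. Between its first Mb and that stretch, bins of 1 Mb held from 14 peaks (6 to 7 Mb) to 79 (27 to 28 Mb, median score 87.2). Each bin from 9 to 17 Mb held 56 to 64 peaks, against 37.8 per Mb on chromosome 4, the densest arm. Those from 1 to 8 Mb held only 14 to 30. The last full Mb of Uextra, 28 to 29 Mb, held 418 peaks with a median score of 96.0. This was higher than on U and the Het sequences by 79.39 (permutation p = 1e-05, the smallest possible). The stretch was picked because it stands out, so the difference cannot decide whether its sequence is like that heterochromatin. The first Mb of Uextra held 145 peaks (Poisson 95% interval 122.4 to 170.6) with a median of 15.2, a difference of -1.46 from U and the Het sequences (bootstrap 95% interval -3.79 to 0.96, permutation p = 0.160). No 1 Mb bin of U or the Het sequences held more than 21 peaks. The first Mb was picked for its number of peaks, so this count cannot decide whether sequence like these is the source. The strong peaks may be copies of sequence from the chromosome arms, but their median exceeded that of the arms by 65.34 and, without the sequence that would pair copies with arm peaks, this cannot be told apart from other sources. No biological explanation was tested, since the design has no group that bears on it.

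The excess of peaks on chromosome 4 lay among peaks below the median score of the list. Among the 50% of the list with the highest scores, chromosome 4 held 11 peaks, 0.611 of its share of the 6 arms by length (exact 95% interval 0.305 to 1.09), where it held 1.43 of its share with all peaks. With only the lowest-scoring 25% of the list left out, a cutoff chosen after the first one, chromosome 4 held 31 peaks, 1.1257 of its share (exact 95% interval 0.766 to 1.59, exact binomial p = 0.501). With so few peaks the interval covers both a full loss and a full persistence of the excess, so peaks near the calling limit cannot be told apart from other weak peaks as its source. Whether the peaks below the median reflect a different chromatin state of chromosome 4 or the behaviour of the peak caller there was not tested.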
